A study of Mus musculus with 12 samples.

How the data were processed

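RNA was sequenced from SV40-immortalised preadipocytes made from adipose tissue of C57Bl/6 mice, in 12 libraries that fall into 4 groups of 3. The groups are Aclyf/f preadipocytes, Acly-/- preadipocytes, Aclyf/f adipocytes and Acly-/- adipocytes. Per the labels' protocols, cells were grown to confluence in DMEM with 10% serum, preadipocytes were taken on day 0, and adipocytes were taken 4 days after a standard adipogenic cocktail with rosiglitazone was added. RNA was isolated with Trizol and libraries were made with an Illumina TruSeq kit, per the same protocols. Aclyf/f cells carry Acly flanked by loxP sites and served as controls. How the gene was deleted, which exons were removed and whether replicates are separate cultures, clones or animals are not given in the sources used here. The p-values below therefore measure only the spread between these libraries.

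The submitters' processing notes name bcl2fastq, Bowtie2 2.2.6, Cufflinks 2.2.1 and the mouse genome build mm10, without a role or an order. The deposited values are FPKM, fragments per kilobase of transcript, scaled to the mapped fragments of the library, per the file headers, in 1 column per library and 24341 genes. No value lies under 0.01, which is a floor: 9384 to 10418 genes per library sit on it exactly. The table is called filtered, but the filter, the gene annotation and the handling of strand are not stated. The table gives a symbol and a locus for each gene. Of the symbols, 23135 were found in a RefSeq table of the same organism, 23024 of them on the same chromosome, and the start in 11857 was 1 base lower than in that table, so starts were raised by 1 here and coordinates are given on mm10 counted from 1. In 27 genes the symbol had been turned into a date, and 4 entries repeat a symbol.

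The table holds no counts, so depth was estimated. Low FPKM values, under 0.3, move in steps of 1 fragment, and the commonest ratio between libraries gave depths that differ by up to 1.93-fold. The method was tested on simulated data. Together with GENCODE transcript lengths of 3000 bases or more it placed the libraries at depths of about 7.1 to 13.8 (in units of 1e+06 fragments). The mean depth relative to the shallowest library was 1.19 in Aclyf/f preadipocytes, 1.47 in Acly-/- preadipocytes, 1.67 in Aclyf/f adipocytes and 1.44 in Acly-/- adipocytes. At these depths most genes under 0.3 FPKM rest on few fragments, so folds for such genes are not given.

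The following was computed here from the deposited FPKM. Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 11777 in number, and 12564 were not. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, as 4 group means with moderated variances that follow a trend with the mean. The 5 contrasts were Acly loss in preadipocytes, Acly loss in adipocytes, differentiation in Aclyf/f cells, differentiation in Acly-/- cells, and the difference between both differentiation contrasts. All p-values for genes are limma's, adjusted by Benjamini-Hochberg over all genes tested within a contrast, and a gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values, and SE is their standard error. Folds given as such are ratios of mean FPKM. Summary tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

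Gene lists were fixed before the data were examined, as were the contrasts, the threshold and most alternatives. There were 27 lists, 21 for pathways or cell states and 6 for other cell types, and Acly is in none of them. The pathway lists cover adipogenic transcription factors, mature adipocyte genes, de novo lipogenesis with NADPH supply, cholesterol synthesis with SREBP2 targets, glucose transport and glycolysis, acetyl-CoA production and the TCA cycle, fatty acid oxidation, respiratory chain subunits, brown and beige adipocyte genes, preadipocyte genes, extracellular matrix, contractile genes with TGF-beta or YAP targets, cell cycle, histone acetyltransferases and deacetylases, interferon-stimulated genes, inflammatory cytokines with NF-kappaB targets, the integrated stress response, the unfolded protein response, p53 targets, NRF2 targets and hypoxia-responsive genes. The 6 others hold markers of macrophages and leukocytes, endothelium, mesothelium and epithelium, skeletal muscle, smooth muscle and pericytes, and bone and cartilage. In 23 lists at least 3 members were tested, and these were tested in each contrast with limma's camera at a preset inter-gene correlation of 0.01. The 115 p-values were adjusted together. Camera asks whether members of a list changed more than other genes. Each test was repeated with an estimated correlation, and with fry, which asks whether members moved one way on balance and makes no comparison with other genes. Of the symbols on the lists, Trarg1, Muc16 and Mymk are not in the table.

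Genes named in the report were chosen by a rule written before the data were examined. Acly, Acss2, Slc2a4 and Mlxipl are named in every contrast. Next come the 8 largest rises and 8 largest falls in the Acly contrasts and in the difference between differentiation contrasts, and the 6 largest of each in the differentiation contrasts. These had to pass the threshold with a mean of at least 5 FPKM in the higher group and values that do not overlap between groups, the last not asked of the difference between contrasts, and predicted genes were left out. For each pathway list described beyond its counts, the 2 largest rises and 2 largest falls among called members are given. Some members that this rule would name are not reported here. For lists of other cell types the 2 members with the highest mean are given. Pparg and Cebpa are named beyond the rule and were chosen after their values were seen.

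Of the genes in the table, 5579 share their listed locus with another gene, 2636 of them tested. Where fragments from overlapping genes were split by the authors' counting, the values of these genes are uncertain. Genes named in the report that share a locus are Acly and Acss2 (a microRNA and an antisense gene), Scd2, Klf9, Pdgfra, Hdac5 and Egfl7 (microRNAs), Srebf1, Cebpd, Pcx, Lss, Timp2, Timp3, Tk1, Ddit3, Ankrd37, Ndufa4l2, Atf5, Runx2, Des, Kcnk3, Cfd, Cnn1 and the small nucleolar RNAs. Prl2c2 and Hist1h4d belong to families of near-identical copies and are uncertain for that reason.

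The fit and the list test were tested on simulated data for the 11777 genes, with 50 genes changed at each of 4 sizes. At a log2 fold change of 1, 96% of changed genes were recovered for Acly loss in preadipocytes, 96% for Acly loss in adipocytes, 96% for differentiation in Aclyf/f cells, 98% for differentiation in Acly-/- cells and 94% for the difference between differentiation contrasts. At 0.5 these shares were 62%, 62%, 76%, 76% and 16%. Among the calls, 3.76%, 5.32%, 5.1%, 5.58% and 6.67% were false. In the simulated list test for adipocytes the shifted list was called and 0 of 22 other lists were. Noise was drawn there independently for each gene, while the correlation estimated in the data reached 0.637 for interferon-stimulated genes. The simulation therefore does not show how often lists of correlated genes are called falsely.

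The alternatives tried were pseudocounts of 0.1 and 0.01, no filter, a filter at 5 FPKM, median-of-ratios rescaling, quantile normalization, no variance trend, fits of single pairs of groups, a replicate block, leaving out each library, and a required absolute log2 fold change of 1. Chosen after the data were seen were rescaling to the same FPKM sum, quantile normalization for lists and single genes, leaving out short and non-polyadenylated RNAs with the same rescaling of the rest, leaving out Acly-/- adipocyte libraries 1 and 2, and leaving out genes that share a locus. The deposited table has 0 columns from samples other than these 12.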

Results

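Gene expression was measured by RNA sequencing in 12 libraries of immortalised mouse preadipocytes, to see how differentiation into adipocytes proceeds with Acly intact or deleted. Acly encodes ATP citrate lyase, the enzyme that makes acetyl-CoA from citrate outside mitochondria. Each genotype had 3 libraries of preadipocytes (day 0) and 3 of adipocytes (day 4). Levels are FPKM, as mean ± SD with n = 3 libraries per group. Estimated depth, relative to the shallowest library, was 1 to 1.43 in Aclyf/f preadipocytes, 1.03 to 1.87 in Acly-/- preadipocytes, 1.51 to 1.93 in Aclyf/f adipocytes and 1.27 to 1.55 in Acly-/- adipocytes. Between 10977 and 11143 genes per library reached 1 FPKM. The 10 most abundant genes took 6.21% to 15.5% of the summed FPKM, the highest share being in Acly-/- preadipocyte library 3. Correlation of log2 values across genes was 0.986 to 0.993 within groups (12 pairs) and 0.819 to 0.964 between groups (54 pairs). The first principal component held 69.7% of the variance. Along it Aclyf/f preadipocytes lay at -50.7 to -49.5, Acly-/- preadipocytes at -47.7 to -44.5, Acly-/- adipocytes at 27.7 to 30.9 and Aclyf/f adipocytes at 66.6 to 67.1.

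Acly itself (chromosome 11, 100476352 to 100528000, mm10) stood at 86.9 ± 2.33 FPKM (SD, n = 3) in Aclyf/f preadipocytes and 754 ± 52.5 FPKM in Aclyf/f adipocytes. In Acly-/- cells it stood at 12.1 ± 0.309 FPKM in preadipocytes and 12.4 ± 1.17 FPKM in adipocytes. Loss of Acly thus went with a 7.19-fold lower level in preadipocytes (log2 fold change -2.75, SE 0.08, limma adjusted p = 1.58e-10) and a 61.0-fold lower level in adipocytes (-5.82, SE 0.08, adjusted p = 8.05e-15). Every Acly-/- library lay below every Aclyf/f library of its stage. Acly rose 8.68-fold with differentiation in Aclyf/f cells (adjusted p = 3.31e-13), while in Acly-/- cells no change was detected (log2 fold change 0.02, adjusted p = 0.795). These values cover the whole gene, and the deleted exons are not given in the sources used here, so fragments from outside the deleted part count toward them.

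Acss2 (chromosome 2, 155518043 to 155562743), which makes acetyl-CoA from acetate, moved in opposite directions at both stages. It stood at 4.51 ± 0.319 FPKM in Aclyf/f and 16.4 ± 1.95 FPKM in Acly-/- preadipocytes, 3.64-fold higher (adjusted p = 4.33e-08), and at 282 ± 11.7 and 70.9 ± 8.83 FPKM in adipocytes, 3.98-fold lower (adjusted p = 3.85e-09). Slc2a4 (chromosome 11, 69942286 to 69948190), the insulin-regulated glucose transporter GLUT4, was under 0.1 FPKM in preadipocytes of both genotypes. In adipocytes it reached 93.7 ± 0.868 FPKM with Acly and 11.7 ± 1.08 FPKM without, 8.06-fold lower (adjusted p = 2.39e-11). Mlxipl (chromosome 5, 135106891 to 135138382), which encodes the glucose-responsive transcription factor ChREBP, was likewise under 0.1 FPKM before differentiation. It reached 27.4 ± 0.155 FPKM in Aclyf/f and 2.07 ± 0.187 FPKM in Acly-/- adipocytes, 13.2-fold lower (adjusted p = 1e-11). In preadipocytes neither gene differed between genotypes in limma (Slc2a4 log2 fold change -0.05, adjusted p = 0.684, and Mlxipl -0.04, adjusted p = 0.701), at levels that rest on few fragments.

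**Figure D1:**
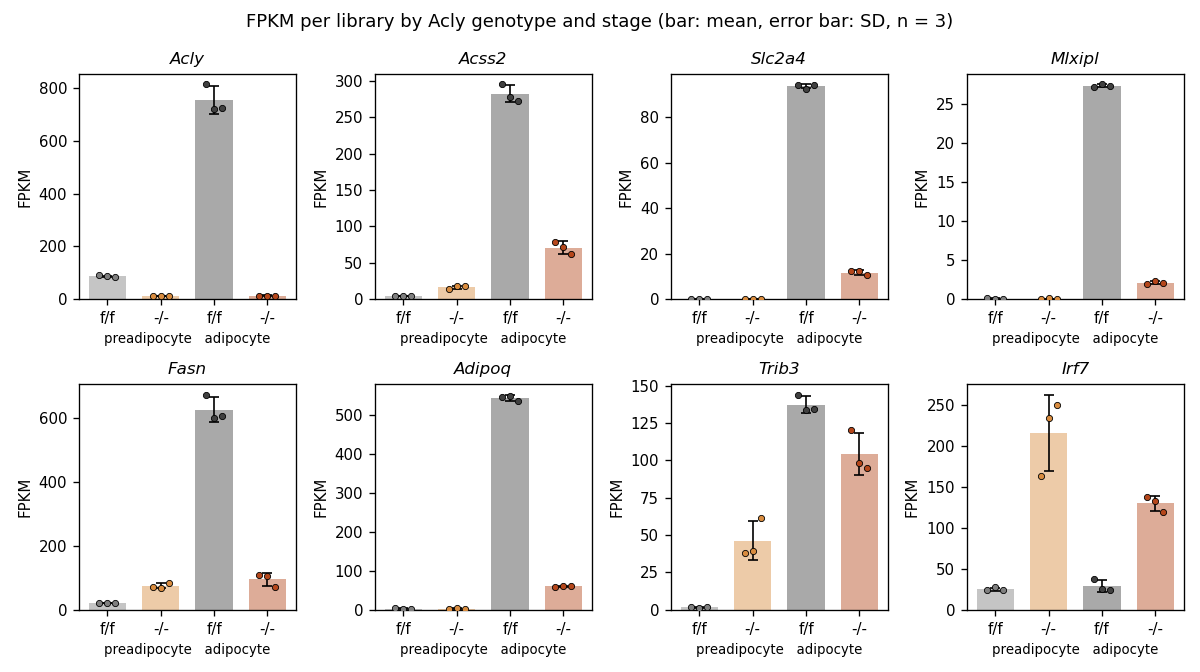
FPKM of 8 genes in each of the 12 libraries (points), with the mean (bar) and SD (error bar, n = 3) by genotype and stage on a linear axis. Acly, Acss2, Slc2a4, Mlxipl, Fasn and Adipoq are lower in every Acly-/- adipocyte library than in every Aclyf/f adipocyte library, and Acss2, Fasn, Trib3 and Irf7 are higher in every Acly-/- preadipocyte library than in every Aclyf/f preadipocyte library.

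The first comparison asked how preadipocytes without Acly differ from those with it, before differentiation. Among the largest rises were Trib3 and genes induced by interferon. Trib3, a pseudokinase gene induced by ATF4, rose from 1.84 ± 0.375 to 46.3 ± 13.1 FPKM, 25.1-fold (log2 fold change 4.03, SE 0.16, adjusted p = 1.99e-09). Ifi44, an interferon-induced gene, rose from 3.51 ± 0.263 to 66.9 ± 16.8 FPKM, 19.1-fold, and the antiviral gene Mx1 from 2.15 ± 0.517 to 33.1 ± 5.54 FPKM, 15.4-fold. Zbp1, a sensor of unusual nucleic acids, rose from 8.26 ± 2.0 to 99 ± 27.4 FPKM, and Oas3, an enzyme gene of the antiviral response that double-stranded RNA activates, from 0.46 ± 0.121 to 14.8 ± 5.74 FPKM. Irf7, the transcription factor that amplifies interferon production, went from 25.1 ± 2.04 to 216 ± 46.1 FPKM, 8.61-fold. Rsad2 (viperin) rose 9.24-fold to 32.4 ± 4.67 FPKM and its neighbour Cmpk2, a nucleotide kinase gene, 8.93-fold to 28.9 ± 5.54 FPKM. Adjusted p of these 7 interferon-related genes was at most 6.53e-08.

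Among the falls were the adjacent membrane protein genes Tmem176b and Tmem176a, at 19.0 ± 0.846 against 1.71 ± 0.293 FPKM and 12.4 ± 1.44 against 1.06 ± 0.17 FPKM, 11.1-fold and 11.7-fold lower. Nov, a secreted matricellular protein, fell 7.3-fold from 53.5 ± 4.6 to 7.31 ± 1.73 FPKM, and the matrix protein gene Fbln7 9.01-fold from 12.4 ± 1.05 to 1.37 ± 0.265 FPKM. Pamr1, a secreted protease-like gene, fell 20.7-fold from 6.97 ± 1.73 to 0.336 ± 0.0474 FPKM. Adjusted p of these 5 genes was at most 2.45e-08. In all, limma called 4966 of 11777 genes, 2325 higher and 2641 lower in Acly-/- preadipocytes, and 602 of these also had an absolute log2 fold change of at least 1 (350 higher, 252 lower). The split depends on scaling: 46.8% of the calls were rises, against 47.3% of 5097 calls after quantile normalization, 34.7% of 4676 after rescaling to the same FPKM sum and 38.0% of 4966 when short and non-polyadenylated RNAs were left out and the rest rescaled to the same sum. Of 23 gene lists, 12 were called.

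Interferon-stimulated genes moved together in Acly-/- preadipocytes, with all 28 of 28 tested members higher and a median log2 fold change of 1.83 (camera adjusted p = 1.09e-22, but 0.0734 with an estimated correlation). Ifi44 and Mx1 rose most. The integrated stress response rose in 20 of 22 members, 21 adjusted over the list alone, with a median of 1.16 (adjusted p = 2.18e-17, and 0.0347 with an estimated correlation). Trib3 led, followed by the amino acid transporter gene Slc7a5, which rose 5.39-fold from 18.4 ± 0.183 to 99 ± 24.2 FPKM. Cholesterol synthesis genes rose in 22 of 24, 23 adjusted over the list alone (median 1.34, adjusted p = 2.36e-19, and 0.0121 with an estimated correlation). Fdps, which makes farnesyl pyrophosphate, went from 62.6 ± 6.78 to 235 ± 22.5 FPKM, 3.76-fold. Lipogenic and NADPH-supplying genes rose in 13 of 22 and fell in 1, with 15 and 1 adjusted over the list alone (median 0.65, adjusted p = 1.6e-07, and 0.0201 with an estimated correlation). The desaturase Scd2 rose 4.63-fold to 581 ± 32.4 FPKM and fatty acid synthase, Fasn, 3.43-fold to 75.3 ± 7.81 FPKM. The fall was in isocitrate dehydrogenase, Idh1, from 101 ± 1.32 to 67.2 ± 3.48 FPKM (log2 fold change -0.59, adjusted p = 6.33e-06).

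Glycolysis genes rose in 15 of 21 and fell in 2, the same counts adjusted over the list alone (median 0.43, adjusted p = 0.000196, and 0.206 with an estimated correlation). Phosphofructokinase Pfkl rose 2.41-fold to 121 ± 20.5 FPKM and phosphoglycerate kinase Pgk1 1.88-fold to 536 ± 43.2 FPKM, while lactate dehydrogenase Ldhb fell 1.64-fold and Pfkfb3 1.72-fold. Hypoxia-responsive genes rose in 11 of 17 and fell in 3 (median 0.43, adjusted p = 0.00221, and 0.175 with an estimated correlation). Ndrg1 went up 5.7-fold to 20.5 ± 2.89 FPKM and the oxidoreductase Ero1l 3.47-fold to 65.7 ± 3.24 FPKM. Angptl4, an inhibitor of lipoprotein lipase, fell 2.36-fold and the peptide hormone gene Adm 1.46-fold. Contractile genes and TGF-beta or YAP targets went down, with 2 rises and 11 falls among 17, 2 and 12 adjusted over the list alone (median -0.59, adjusted p = 0.000614, and 0.148 with an estimated correlation). The myosin light chain gene Myl9 fell 4.67-fold from 142 ± 10.1 to 30.3 ± 4.52 FPKM and calponin, Cnn1, 4.74-fold from 19.4 ± 0.915 to 4.09 ± 0.464 FPKM. Activin A, Inhba, rose 2.7-fold to 40.4 ± 4.99 FPKM and Amotl2 1.34-fold to 81.4 ± 7.72 FPKM. Preadipocyte genes rose in 7 of 13 and fell in 2 (median 0.25, adjusted p = 0.0128, and 0.198 with an estimated correlation). Wnt10b, a Wnt ligand that holds back adipogenesis, rose from 0.137 ± 0.0834 to 4.71 ± 0.941 FPKM (log2 fold change 2.32, adjusted p = 1.05e-08). Sox9 rose 3.33-fold to 7.94 ± 0.768 FPKM. The progenitor receptor Pdgfra fell 1.82-fold to 72.1 ± 7.08 FPKM and the integrin gene Itgb1 1.37-fold to 226 ± 19.8 FPKM.

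Fatty acid oxidation genes fell in 12 of 22 and rose in 2 without Acly in preadipocytes, with 13 and 2 adjusted over the list alone (median -0.22, adjusted p = 0.0075, and 0.0955 with an estimated correlation). Hsd17b4 fell 1.7-fold and Etfdh 1.42-fold, and Acaa1a rose 1.7-fold. Eci1 rose 1.2-fold (adjusted p = 0.0328), a call that ended when Aclyf/f preadipocyte library 1, 2 or 3 (adjusted p 0.0635, 0.0602 or 0.0942) or Acly-/- preadipocyte library 1 or 3 (0.0727 or 0.112) was left out, and after rescaling to the same FPKM sum (0.129). NRF2 and antioxidant genes were called narrowly, with 8 rises and 2 falls among 20 (median 0.08, adjusted p = 0.0487, and 0.198 with an estimated correlation). Srxn1, which repairs oxidised peroxiredoxins, rose 1.66-fold and Gsta4 2.6-fold, while Gpx3 fell 1.5-fold and Gstm2 1.39-fold. That list lost its call without Aclyf/f preadipocyte library 2 (0.0550) or 3 (0.0607), Acly-/- preadipocyte library 1 (0.0692) or 3 (0.0592), Aclyf/f adipocyte library 1 (0.0519) or 2 (0.0511) and Acly-/- adipocyte library 1 (0.0522).

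Adipocyte programmes showed no call as lists before differentiation. Adipogenic transcription factors rose in 1 and fell in 9 of 16, with 2 and 9 adjusted over the list alone (median -0.28, adjusted p = 0.0714). Srebf1, which drives lipid synthesis genes, rose 2.05-fold to 50.3 ± 8.78 FPKM, while Cebpd fell 3.29-fold to 2.92 ± 0.969 FPKM and Klf9 2.58-fold to 12.8 ± 0.521 FPKM. Pparg, the master regulator of adipogenesis, was 47.29 ± 4.75 FPKM in Aclyf/f and 35.21 ± 1.24 FPKM in Acly-/- preadipocytes (adjusted p = 0.00136), and Cebpa, its partner, 30.29 ± 3.39 and 12.82 ± 2.33 FPKM (adjusted p = 2.04e-05). Mature adipocyte genes rose in 6 and fell in 9 of 32, with the same counts adjusted over the list alone. Their median was 0.01, while the mean was -0.07 and the test pointed down (adjusted p = 0.875). Caveolin, Cav1, rose 2.32-fold and the triglyceride synthesis gene Dgat2 2.78-fold, whereas the fatty acid binding protein gene Fabp4 fell 2.53-fold from 507 ± 9.49 to 201 ± 19.9 FPKM and Cdo1 2.62-fold. Other lists without a call were acetyl-CoA and TCA genes (6 rises and 3 falls of 29, adjusted p = 0.454), respiratory chain (9 and 1 of 32, or 5 and 1 adjusted over the list alone, 0.151), extracellular matrix (6 and 9 of 27, 0.317), cell cycle (5 and 6 of 30, 0.67), histone acetyltransferases and deacetylases (5 and 6 of 23, 0.53), inflammatory genes (3 and 5 of 16, 0.467), the endoplasmic reticulum unfolded protein response (7 and 0 of 18, or 5 and 0 adjusted over the list alone, 0.0522) and p53 targets (4 and 5 of 17, 0.819). The unfolded protein response was called without Aclyf/f preadipocyte library 3 (0.0396) or Acly-/- preadipocyte library 3 (0.0316), and after median-of-ratios rescaling (0.0489).

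The second comparison asked how adipocytes without Acly differ from those with it, 4 days into differentiation. Thrsp, Rbp4, Retn and Gpd1 were among the largest falls. Thrsp, a nuclear protein that promotes lipogenesis, fell from 365 ± 50.5 to 7.72 ± 0.963 FPKM, 47.2-fold (log2 fold change -5.39, SE 0.11, adjusted p = 1.7e-12). The retinol carrier Rbp4 fell 29.2-fold from 183 ± 6.71 to 6.27 ± 1.29 FPKM, and resistin, Retn, 17.3-fold from 844 ± 82.1 to 48.8 ± 2.4 FPKM. Glycerol-3-phosphate dehydrogenase, Gpd1, which supplies the glycerol backbone of triglycerides, fell 17.5-fold from 80.0 ± 3.66 to 4.57 ± 0.446 FPKM. The basement membrane laminin gene Lama4 went from 44.0 ± 0.148 to 1.19 ± 0.263 FPKM, the secreted glycoprotein gene Lrg1 from 32.6 ± 3.56 to 0.897 ± 0.259 FPKM, and Cox7a1, a cytochrome oxidase subunit of muscle and brown fat, from 30.2 ± 5.03 to 1.25 ± 0.449 FPKM. These were falls of 36.9-fold, 36.4-fold and 24.2-fold. Adjusted p of these 7 genes was at most 2.16e-09.

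Protein-coding genes among the largest rises in Acly-/- adipocytes were Prl2c2, Cd68 and Ifi44. Prl2c2, a placental hormone gene of a family of near-identical copies, was 3.0 ± 0.315 FPKM in Aclyf/f and 91.3 ± 18.5 FPKM in Acly-/- adipocytes (30.5-fold, adjusted p = 1.59e-10). Cd68, a lysosomal membrane glycoprotein abundant in macrophages, rose 21.8-fold from 1.5 ± 0.344 to 32.6 ± 3.12 FPKM (adjusted p = 6.31e-10). Ifi44 rose 14-fold from 3.51 ± 0.665 to 49.0 ± 5.64 FPKM (adjusted p = 1.68e-09). In all, 6452 genes were called, 3013 higher and 3439 lower, and 936 of them had an absolute log2 fold change of at least 1 (416 higher, 520 lower). Rises made up 46.7% of calls, against 51.7% of 6426 after quantile normalization, 36.4% of 6073 after rescaling to the same FPKM sum and 38.1% of 6359 with short and non-polyadenylated RNAs left out and the rest rescaled to the same sum. Of 23 lists, 17 were called, 8 upward and 9 downward.

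Mature adipocyte genes fell in 28 of 32 and rose in 0, the same counts adjusted over the list alone, with a median log2 fold change of -1.22 (adjusted p = 1.95e-13, and 0.00449 with an estimated correlation). Retn and Gpd1 fell most. Lipogenic genes fell in 19 of 22 and rose in 1, with 20 and 1 adjusted over the list alone (median -1.06, adjusted p = 1.74e-10, and 0.0121 with an estimated correlation). Thrsp and Mlxipl led the falls, and Idh1 rose from 204 ± 3.74 to 291 ± 12.9 FPKM (log2 fold change 0.51, adjusted p = 1.3e-05). Acetyl-CoA and TCA genes fell in 24 of 29, 25 adjusted over the list alone (median -0.60, adjusted p = 7.5e-10, and 0.0196 with an estimated correlation). After Acss2 came the pyruvate dehydrogenase subunit Pdhb, 3.00-fold lower at 195 ± 9.78 against 587 ± 11.8 FPKM. Fatty acid oxidation genes fell in 20 of 22 and rose in 1 (median -0.73, adjusted p = 6.42e-08, and 0.0121 with an estimated correlation). The peroxisomal enzyme gene Ehhadh fell 7.19-fold to 3.04 ± 0.142 FPKM and the acyl-CoA dehydrogenase Acadm 2.19-fold to 100 ± 6.19 FPKM. The carnitine acyltransferase Cpt1a rose 1.8-fold to 8.8 ± 0.643 FPKM. Glycolysis genes fell in 18 of 21 (median -1.19, adjusted p = 1.95e-10, and 0.0723 with an estimated correlation), led by Slc2a4 and by aldolase C, Aldoc, at 8.55 ± 0.471 against 0.661 ± 0.0776 FPKM. Cholesterol synthesis genes, higher in Acly-/- preadipocytes, were lower in Acly-/- adipocytes in 15 of 24, 16 adjusted over the list alone (median -0.50, adjusted p = 0.000208, and 0.157 with an estimated correlation). Pmvk fell 3.73-fold from 192 ± 17.6 to 51.5 ± 2.74 FPKM and lanosterol synthase, Lss, 2.38-fold from 43.4 ± 0.817 to 18.3 ± 1.94 FPKM.

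Cell cycle genes were lower in Acly-/- adipocytes in 29 of 30 (median -0.75, adjusted p = 2.2e-11, and 0.00736 with an estimated correlation). Thymidine kinase, Tk1, fell 2.58-fold from 100 ± 3.78 to 39.0 ± 1.39 FPKM and the proliferation marker Mki67 2.22-fold from 34.8 ± 1.86 to 15.6 ± 1.7 FPKM. Targets of p53 rose in 11 of 17 and fell in 1 (median 0.71, adjusted p = 5.82e-05, and 0.0131 with an estimated correlation). Plk2, a kinase gene, rose 5.23-fold from 5.42 ± 0.377 to 28.3 ± 2.9 FPKM and the receptor gene Eda2r 4.87-fold from 4.19 ± 0.52 to 20.4 ± 2.34 FPKM, while the pro-apoptotic gene Bbc3 fell 1.77-fold. Hypoxia-responsive genes fell in 15 of 17, 16 adjusted over the list alone (median -0.62, adjusted p = 9.22e-07, and 0.0698 with an estimated correlation). The oxygen-sensing hydroxylase gene Egln3 was 13.8 ± 2.02 FPKM in Aclyf/f and 0.484 ± 0.355 FPKM in Acly-/- adipocytes, and Ankrd37 fell 5.92-fold. Respiratory chain subunits fell in 19 of 32 and rose in 2 (median -0.37, adjusted p = 0.00133, and 0.406 with an estimated correlation). Ndufs8 and Uqcrfs1 fell 1.77-fold and 1.76-fold. Ndufa4 rose 1.29-fold and Cox7b 1.22-fold, the latter no longer called without Acly-/- adipocyte library 3 (adjusted p = 0.0531) or after rescaling to the same FPKM sum (0.0827). That list was not called when Acly-/- adipocyte libraries 1 and 2 were both left out (adjusted p = 0.0842).

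Matrix genes were higher in Acly-/- adipocytes in 24 of 27 and lower in 1 (median 1.03, adjusted p = 1.4e-11, and 0.102 with an estimated correlation). The metalloproteinase inhibitor Timp2 rose 4.68-fold from 27.2 ± 4.25 to 127 ± 11.7 FPKM and the gelatinase Mmp2 3.56-fold from 12.6 ± 2.54 to 44.7 ± 4.49 FPKM, while decorin, Dcn, fell 2.06-fold. Contractile genes and TGF-beta or YAP targets rose in 12 of 17 and fell in 2, with 13 and 2 adjusted over the list alone (median 0.63, adjusted p = 0.000122, and 0.118 with an estimated correlation). Connective tissue growth factor, Ctgf, rose 4.88-fold to 30.6 ± 7.16 FPKM and smooth muscle actin, Acta2, 2.58-fold to 44.8 ± 4.11 FPKM. Tgfb1 fell 1.72-fold. Actg2, under 0.5 FPKM, was called lower (adjusted p = 0.0179) but not without Aclyf/f adipocyte library 1 (0.0515) or 2 (0.0622). Preadipocyte genes rose in 9 of 13 and fell in 1 (median 0.58, adjusted p = 0.000425, and 0.0981 with an estimated correlation). The stem cell antigen gene Ly6a rose 5.08-fold to 649 ± 27.1 FPKM and Wisp2, a secreted Wnt target, 3.57-fold to 30.2 ± 2.91 FPKM, and Nt5e went down from 2.44 ± 0.219 to 0.0979 ± 0.0479 FPKM. Unfolded protein response genes rose in 12 of 18 and fell in 3 (median 0.50, adjusted p = 0.00131, and 0.0829 with an estimated correlation). The chaperone genes Pdia3 and Calr rose 2.4-fold and 2.11-fold, and Sel1l and Xbp1 fell 1.42-fold and 1.21-fold.

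Interferon-stimulated genes stayed higher without Acly after differentiation, with 26 rises and 2 falls among 28 (median 1.30, adjusted p = 3.42e-12, and 0.16 with an estimated correlation). Ifit3 rose 6.04-fold from 15.5 ± 4.95 to 93.4 ± 6.84 FPKM. The immunoproteasome subunit Psmb9 fell 1.78-fold from 127 ± 22.1 to 71.2 ± 4.36 FPKM (adjusted p = 0.00107). Psmb8 fell 1.3-fold at an adjusted p of 0.0447, a call that 9 of the 12 libraries each ended when left out. Without Acly-/- adipocyte library 1, 2 or 3 its adjusted p was 0.106, 0.0979 or 0.0697, without Aclyf/f adipocyte library 1 or 2 it was 0.177 or 0.0503, without Acly-/- preadipocyte library 2 it was 0.0531, and without Aclyf/f preadipocyte library 1, 2 or 3 it was 0.053, 0.0515 or 0.0531. Inflammatory genes rose in 7 of 16 and fell in 4, with 8 and 5 adjusted over the list alone (median 0.06, adjusted p = 0.0415, and 0.206 with an estimated correlation). The chemokine gene Ccl7 rose 8.41-fold from 6.63 ± 0.979 to 55.7 ± 3.96 FPKM and serum amyloid Saa3 9.21-fold from 2.22 ± 1.05 to 20.4 ± 2.37 FPKM, while Relb fell 1.61-fold and Tnfaip3 1.39-fold. The list lost its call without Acly-/- preadipocyte library 1, 2 or 3 (0.0505, 0.0537 or 0.0665) and with a pseudocount of 0.1 (0.104).

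Pathway lists without a call in adipocytes were adipogenic transcription factors, the integrated stress response, NRF2 targets and histone acetyltransferases and deacetylases. Adipogenic transcription factors rose in 2 and fell in 8 of 16 (median -0.21, adjusted p = 0.178). Cebpd was 1.86-fold and Ebf1 1.44-fold higher, and the transcription factor genes Stat5a and Stat5b were 2.73-fold and 2.69-fold lower. Pparg, at 160.9 ± 1.18 and 147.5 ± 13.7 FPKM, did not differ detectably (adjusted p = 0.208), and Cebpa was 134.7 ± 17.3 against 76.05 ± 13.1 FPKM (adjusted p = 0.000287). The integrated stress response rose in 7 and fell in 7 of 22, with a median of -0.06 and a mean of -0.03 while the test pointed up (adjusted p = 0.913). Slc7a11 rose 1.87-fold and Atf5 1.46-fold, and Fgf21 fell 2.34-fold and Psat1 1.55-fold. NRF2 targets rose in 6 and fell in 5 of 20 (adjusted p = 0.819). Histone acetyltransferases and deacetylases, whose substrate or product is acetylated histone, rose in 4 and fell in 6 of 23 (median -0.08, adjusted p = 0.681). Kat2a rose 1.46-fold, and Sirt1 1.34-fold, the latter not called after rescaling to the same FPKM sum (0.0531). Hdac11 fell 2.34-fold from 10.5 ± 0.254 to 4.48 ± 0.406 FPKM and Hdac5 1.67-fold.

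Differentiation of Aclyf/f cells asked which genes change when Acly is intact, and Retn, Cidec and Thrsp were among the genes that rose most. Resistin, Retn, rose from 0.287 ± 0.0469 to 844 ± 82.1 FPKM (log2 fold change 9.36, SE 0.13, adjusted p = 1.81e-15). The lipid droplet gene Cidec went from 0.0589 ± 0.0847 to 448 ± 6.68 FPKM, Thrsp from 0.0432 ± 0.0575 to 365 ± 50.5 FPKM, and adipogenin, Adig, from 0.0764 ± 0.115 to 156 ± 23.5 FPKM. G0s2, an inhibitor of lipolysis, rose 569-fold to 320 ± 41.1 FPKM and adiponectin, Adipoq, 174-fold to 544 ± 7.05 FPKM. On the log2(FPKM + 1) scale, falls were led by the chemokine genes Cxcl12 and Ccl2. Cxcl12 was 152-fold lower at 10.9 ± 2.33 against 1650 ± 12.7 FPKM, and Ccl2 170-fold lower at 1.37 ± 0.276 against 233 ± 7.19 FPKM. Thrombospondin, Thbs1, fell 100-fold from 1500 ± 103 FPKM, pleiotrophin, Ptn, 179-fold from 129 ± 15.6 FPKM, and the Wnt agonist gene Rspo2 78.7-fold from 78.9 ± 8.67 FPKM. The interleukin-33 receptor gene Il1rl1 went from 68.0 ± 2.98 to 0.0488 ± 0.015 FPKM. Acss2 rose 62.6-fold, and the log2 fold changes of Slc2a4 and Mlxipl were 6.43 and 4.73. Adjusted p of the 12 genes named here for the size of their change was at most 1.4e-13.

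Differentiation of Acly-/- cells, asked about in the same way, also raised adipocyte genes. G0s2 rose 341-fold to 293 ± 41.6 FPKM (log2 fold change 7.31, SE 0.15, adjusted p = 1.44e-13) and Cidec from 0.198 ± 0.172 to 181 ± 16.5 FPKM. The taurine synthesis gene Cdo1 rose 119-fold to 255 ± 11.1 FPKM, perilipin, Plin1, 173-fold to 98.4 ± 6.8 FPKM, the fatty acid transporter Cd36 from 0.284 ± 0.0893 to 98.9 ± 8.97 FPKM and the sulfotransferase Sult1a1 from 0.182 ± 0.0344 to 61.0 ± 4.19 FPKM. Thbs1 fell 43.1-fold from 1270 ± 117 FPKM, Rspo2 48.8-fold from 80.1 ± 3.44 FPKM, and the metalloproteinase inhibitor Timp3 49.5-fold from 65.3 ± 10.7 FPKM. Ptn fell 29.2-fold, Ccl2 19.5-fold, and the ectoenzyme gene Enpp1 71.9-fold from 26.2 ± 2.23 FPKM. Adjusted p of these 12 genes was at most 5.42e-12. Acss2 rose 4.32-fold (adjusted p = 1e-09), and the log2 fold changes of Slc2a4 and Mlxipl were 3.57 and 1.57. Limma called 8537 genes in Aclyf/f cells (4301 up, 4236 down) and 7232 in Acly-/- cells (3583 up, 3649 down). With an absolute log2 fold change of at least 1 the counts were 2766 (1510 up, 1256 down) and 1535 (727 up, 808 down).

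Adipogenic transcription factors rose in both genotypes, in 13 of 16 with 2 falls in Aclyf/f cells (median 1.34, adjusted p = 0.000208) and in 12 with 1 fall in Acly-/- cells (median 0.91, adjusted p = 7.22e-06). Klf15 rose 29.8-fold with Acly and 21-fold without, and Nr1h3, the oxysterol receptor LXR alpha, 24.8-fold and 23-fold. Nr3c1 and Ebf1 fell 1.47-fold and 1.36-fold in Aclyf/f cells, and Stat5b 1.33-fold in Acly-/- cells. Mature adipocyte genes rose in all 32 in Aclyf/f cells (median 4.08, adjusted p = 2.58e-19) and in 30 of 32 in Acly-/- cells, 31 adjusted over the list alone (median 2.75, adjusted p = 2.19e-21). Lipogenic genes rose in 21 of 22 and fell in 1 with Acly (median 2.76, adjusted p = 4.33e-11), and rose in 17 and fell in 4 without it (median 0.83, adjusted p = 5.59e-05, but 0.0561 with an estimated correlation). The desaturase Scd1 rose 59.1-fold to 1430 ± 7.56 FPKM in Aclyf/f cells and 6.84-fold to 511 ± 62.8 FPKM in Acly-/- cells. The elongase Elovl6 fell 2.33-fold and 3.7-fold, and Fads2 fell 2.23-fold in Acly-/- cells. Acetyl-CoA and TCA genes rose in 29 of 29 in both (medians 1.38 and 0.89, adjusted p = 1.36e-12 and 7.93e-13). Pyruvate carboxylase, Pcx, rose 48.1-fold to 640 ± 38.8 FPKM with Acly and 13.0-fold to 225 ± 13.7 FPKM without, and Acss3 rose to 21.7 ± 4.04 FPKM in Acly-/- cells. Fatty acid oxidation genes rose in 20 and 19 of 22 and fell in 2 and 2 (medians 1.10 and 0.71, adjusted p = 7.85e-07 and 5.26e-06). Ehhadh rose 33.8-fold with Acly and to 3.04 ± 0.142 FPKM without, and Echs1 5.6-fold and 3.44-fold. Cpt1a fell 6.49-fold and 2.88-fold, and the carnitine carrier Slc25a20 1.22-fold and 1.37-fold, the former not called without Aclyf/f preadipocyte library 3 (0.0507) or Aclyf/f adipocyte library 3 (0.0613).

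Matrix genes fell with differentiation, in 25 of 27 with 2 rises in Aclyf/f cells (median -1.81, adjusted p = 5.83e-10, and 0.128 with an estimated correlation) and in 17 with 4 rises in Acly-/- cells (median -0.56, adjusted p = 0.000257, and 0.327). Fibrillin, Fbn1, fell 17.9-fold and Timp2 12.6-fold in Aclyf/f cells, and Timp3 49.5-fold and fibronectin, Fn1, 10.2-fold in Acly-/- cells. The basement membrane collagen genes Col4a2 and Col4a1 rose 7.4-fold and 6.95-fold with Acly and 8.28-fold and 8.59-fold without. Contractile genes and TGF-beta or YAP targets fell in 14 of 17 with 3 rises (median -2.59, adjusted p = 6.76e-06, and 0.0772 with an estimated correlation) and in 12 with 2 rises (median -0.82, adjusted p = 0.000285, and 0.131). Thbs1 led both falls on the log2(FPKM + 1) scale, followed by Myl9, 42.4-fold lower in Aclyf/f cells, and Inhba, 15.9-fold lower in Acly-/- cells. Amotl2 rose 1.25-fold with Acly and 1.32-fold without. In Aclyf/f cells cell cycle genes fell in 18 of 30 with 4 rises (median -0.28, adjusted p = 0.0286, and 0.156 with an estimated correlation), a call that ended after rescaling to the same FPKM sum (0.0529), and in 30 of 30 in Acly-/- cells (median -1.01, adjusted p = 2.75e-12). Rrm2 and Mcm4 fell 1.68-fold and 1.8-fold, and E2f1 and Tk1 rose 1.56-fold and 1.3-fold, with Acly. Without it Birc5 fell 2.99-fold and Mki67 2.79-fold. The integrated stress response rose in 22 of 22 with Acly (median 2.32, adjusted p = 6.29e-11, and 0.0734 with an estimated correlation) and in 19 without it (median 0.55, adjusted p = 9.94e-07, and 0.148). Trib3 rose 74.4-fold to 137 ± 5.54 FPKM and Mthfd2 14.4-fold in Aclyf/f cells, and Vldlr 7.03-fold and Ddit3 3.57-fold in Acly-/- cells.

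Cholesterol synthesis genes took opposite directions, with 23 of 24 up in Aclyf/f cells (median 1.42, adjusted p = 8.01e-08, and 0.0734 with an estimated correlation) and 4 up and 14 down in Acly-/- cells, 4 and 15 adjusted over the list alone (median -0.33, adjusted p = 0.0128, and 0.322). Insig1 rose 9.73-fold and Pmvk 9.79-fold with Acly. Without it Insig1 rose 1.93-fold and Dhcr7 1.38-fold, while squalene epoxidase, Sqle, fell 2.52-fold. Hypoxia-responsive genes rose in 12 and fell in 4 of 17 with Acly (adjusted p = 0.0217, and 0.296 with an estimated correlation) and rose in 3 and fell in 12 without it, 3 and 13 adjusted over the list alone (adjusted p = 0.00814, and 0.231). Glycolysis genes rose in 16 and fell in 2 of 21 (adjusted p = 2.52e-05, and 0.16 with an estimated correlation), and in Acly-/- cells rose in 5 and fell in 12, which was not called (0.0827) except after rescaling to the same FPKM sum (0.0332). Further calls in both genotypes were rises of the respiratory chain (31 and 31 of 32, adjusted p = 2.72e-09 and 4.89e-09, or 0.15 and 0.155 with an estimated correlation) and falls of preadipocyte genes (11 and 11 of 13, with 1 and 0 rises, adjusted p = 6.82e-05 and 2.11e-06, or 0.0734 and 0.0487), interferon-stimulated genes (19 and 25 of 28, with 4 and 0 rises, 0.0128 and 3.94e-08, or 0.614 and 0.26) and inflammatory genes (11 and 9 of 16, with 3 and 4 rises, 0.00615 and 0.0217, or 0.118 and 0.16). Targets of p53 rose in 10 and fell in 2 of 17 in Acly-/- cells (0.0309, and 0.0955 with an estimated correlation) and were not called in Aclyf/f cells (6 rises, 9 falls, 0.366). Without a call in Aclyf/f and Acly-/- cells were the unfolded protein response (0.353 and 0.585), NRF2 targets (0.178 and 0.686) and histone acetyltransferases and deacetylases (0.524 and 0.0843).

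**Figure D2:**
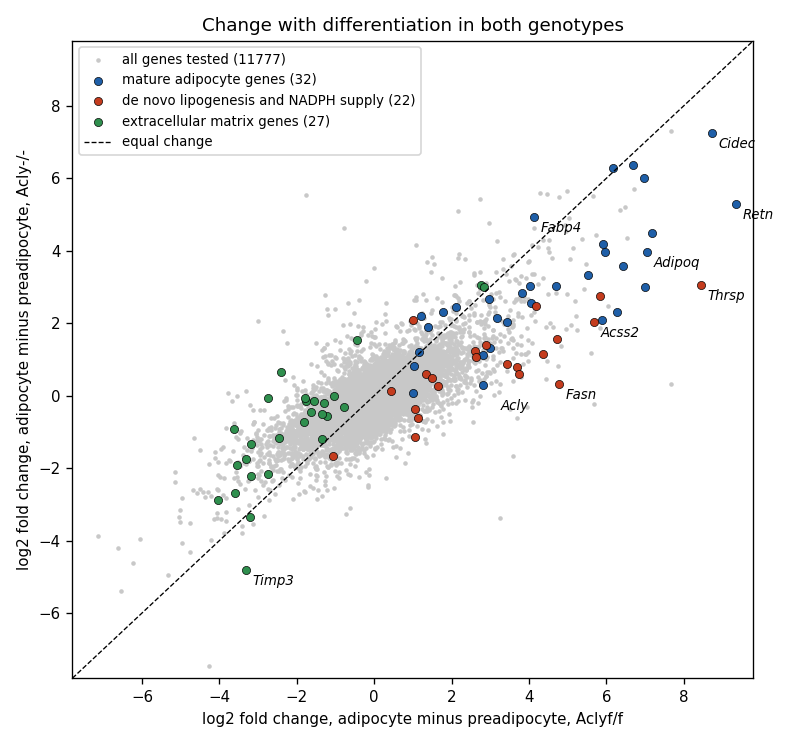
Log2 fold change with differentiation in Aclyf/f cells (horizontal axis) and Acly-/- cells (vertical axis) for the 11777 genes tested, with 3 gene lists in colour and a dashed line of equal change. Most mature adipocyte and lipogenic genes lie below the line, and most matrix genes lie above it.

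The difference between both differentiation contrasts tests whether loss of Acly changed the response itself. Thrsp, Fasn and Retn were among the genes that gained less without Acly. Thrsp gained less by 5.40 on the log2 scale (difference -5.40, SE 0.16, adjusted p = 1.99e-10). Fasn had a difference of -4.45 (SE 0.18, adjusted p = 1.51e-09), going from 21.9 ± 0.706 to 627 ± 39.5 FPKM with Acly and from 75.3 ± 7.81 to 95.9 ± 20.5 FPKM without. Trib3 had one of -4.43, since it rose from a higher start in Acly-/- cells to 105 ± 14 FPKM. Ndufa4l2, which shares its locus with Shmt2, had -4.29, reaching 22.1 ± 2.62 FPKM with Acly and 1.86 ± 0.836 FPKM without. Cox7a1 had -4.27 and Retn -4.07. For the genes named throughout, differences were -3.08 for Acly, -3.64 for Acss2, -2.86 for Slc2a4 and -3.16 for Mlxipl. Adjusted p of these genes was at most 4.27e-08. Prl2c2 had a positive difference of 3.84 (adjusted p = 3.46e-08), falling from 54.4 ± 12.5 to 3.0 ± 0.315 FPKM with Acly and standing at 86.7 ± 11.8 and 91.3 ± 18.5 FPKM without. In all 5908 genes were called, 2795 with a positive and 3113 with a negative difference, and 1459 had an absolute difference of at least 1 (672 and 787).

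Attenuation was the common form of the difference among genes chosen by their change in Aclyf/f cells. Of 1510 genes that rose by at least 1 on the log2 scale in Aclyf/f cells, 1157 (76.6%) rose less in Acly-/- cells by this test and 63 (4.17%) rose more. Of 1256 that fell by as much, 939 (74.8%) fell less and 45 (3.58%) more. In 20 simulations with noise but no such difference by genotype, the counts of genes changing less or more were at most 1. Both sets were chosen by the Aclyf/f change, which also enters the difference with a minus sign. Differences without a common direction would therefore lean toward attenuation in these sets, and the simulations do not measure that lean. Median changes were 1.52 against 0.79 for the first set and -1.51 against -0.89 for the second. Across the 11777 genes, which are not independent replicates, Pearson's r between both contrasts was 0.75 and Spearman's rho 0.681. Both contrasts called 2652 genes up, against 1309 for independent lists, 2602 down, against 1312, and 575 in opposite directions, against 2621. These contrasts share no libraries. The effects of Acly loss at both stages, which also share no libraries, had an r of 0.14 and a rho of 0.0921 across genes. Among 2920 genes called at both stages, 835 were higher at both (595 for independent lists), 898 lower at both (771) and 1187 opposite (1355).

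Lists with a negative difference were led by cholesterol synthesis, in 24 of 24 genes (median -1.61, adjusted p = 2.64e-16), with Pmvk at -3.11 and the decarboxylase Mvd at -2.88. Lipogenic genes had 20 negative and 1 positive of 22, with 21 and 1 adjusted over the list alone (median -1.73, adjusted p = 2.88e-14), the positive one being Idh1 at 1.10. Mature adipocyte genes had 22 negative and 5 positive of 32 (median -1.44, adjusted p = 8.55e-09). Retn and complement factor D, Cfd, at -4.00, had the largest negative differences, and the amine oxidase Aoc3 (0.98) and Fabp4 (0.80) the largest positive ones. Acetyl-CoA and TCA genes had 20 negative of 29 (median -0.49, adjusted p = 9.43e-08), with Acss2 first and Pcx at -1.85. Fatty acid oxidation had 14 negative and 1 positive of 22, or 15 and 1 adjusted over the list alone (median -0.39, adjusted p = 0.000371), with Ehhadh at -2.15, Acaa1a at -1.69 and Cpt1a at 1.05. Cell cycle genes had 26 negative and 2 positive of 30, or 27 and 2 adjusted over the list alone (median -0.67, adjusted p = 1.26e-08), with Tk1 at -1.57, E2f1 at -1.07 and Rrm2 at 0.43. Mcm4, at 0.26 (adjusted p = 0.0388), lost its call without Aclyf/f preadipocyte library 2 (0.0872) or 3 (0.0786), Acly-/- preadipocyte library 3 (0.0721), Aclyf/f adipocyte library 1 (0.0855) or 3 (0.0508) or Acly-/- adipocyte library 1, 2 or 3 (0.0583, 0.0634 or 0.0672), and after rescaling to the same FPKM sum (0.135). These 6 lists kept their calls with an estimated correlation, at adjusted p of 0.00736 to 0.0487.

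Integrated stress genes had 19 negative differences of 22, 20 adjusted over the list alone (median -1.41, adjusted p = 3.48e-11, and 0.0734 with an estimated correlation), with Trib3 and the folate enzyme gene Mthfd2 (-2.64) first. This mostly restates a preadipocyte rise (median 1.16), since the adipocyte median was -0.06. For cholesterol synthesis these were 1.34 and -0.50. Glycolysis had 20 negative and 1 positive of 21 (median -1.51, adjusted p = 3.42e-12, and 0.0561), with Aldoc at -3.28, Slc2a4 next and Ldhb at 0.58. Hypoxia-responsive genes had 14 negative and 1 positive of 17, or 15 and 1 adjusted over the list alone (median -1.38, adjusted p = 2.36e-07, and 0.0591), with Egln3 at -3.87, Ero1l at -3.12 and Angptl4 at 0.76. Respiratory chain subunits had 19 negative of 32, 20 adjusted over the list alone (median -0.45, adjusted p = 0.000725, and 0.387), with Uqcrq at -1.26 and Cyc1 at -1.13. Interferon-stimulated genes had 14 negative and 1 positive of 28, or 15 and 1 adjusted over the list alone (median -0.62, adjusted p = 0.00338, and 0.553), with Psmb9 at -2.23 and Psmb8 at -1.68. The positive one was Ifit2 at 0.50 (adjusted p = 0.0434), not called without Aclyf/f preadipocyte library 1, 2 or 3 (0.0726, 0.0693 or 0.0654), Acly-/- preadipocyte library 1 or 3 (0.0587 or 0.103), Aclyf/f adipocyte library 2 or 3 (0.103 or 0.0961) and Acly-/- adipocyte library 1 or 2 (0.107 or 0.0715), and after rescaling to the same FPKM sum (0.0779).

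Positive differences were found for matrix genes, in 22 of 27 with 1 negative (median 1.10, adjusted p = 1.33e-10, and 0.118 with an estimated correlation). Mmp2 had 3.08 and Timp2 2.71, and Timp3 had -1.51, or -0.48 with a pseudocount of 0.1, which ended its call (adjusted p = 0.141). Contractile genes and TGF-beta or YAP targets had 14 positive and 1 negative of 17, or 14 and 2 adjusted over the list alone (median 1.36, adjusted p = 5.07e-07, and 0.0657). Acta2 had 2.99 and Myl9 2.77, while Tgfb1 had -0.43 (adjusted p = 0.0222), not called without Aclyf/f preadipocyte library 3 (0.06), Aclyf/f adipocyte library 1 (0.0528) or Acly-/- adipocyte library 1 (0.0594). Inflammatory genes had 10 positive and 1 negative of 16, or 10 and 2 adjusted over the list alone (median 0.77, adjusted p = 0.000902, and 0.0734), with Cxcl12 at 3.27, Saa3 at 3.09 and Cxcl1 at -0.75. Targets of p53 had 9 positive and 1 negative of 17 (median 0.55, adjusted p = 0.000392, and 0.0201), with the death receptor Fas at 2.19, Pmaip1 at 1.81 and Bbc3 at -0.70. No call was made for adipogenic transcription factors (5 positive and 5 negative of 16, or 6 and 5 adjusted over the list alone, 0.935), in which Cebpd had 2.33, Klf9 1.09, Srebf1 -1.56 and Stat5a -1.49. Pparg had 0.28 (adjusted p = 0.0592) and Cebpa 0.37 (adjusted p = 0.148). The lists of preadipocyte genes (5 and 4 of 13, or 6 and 4 adjusted over the list alone, 0.337), histone acetyltransferases and deacetylases (2 and 8 of 23, or 2 and 7, 0.504), the unfolded protein response (9 and 4 of 18, 0.123) and NRF2 targets (2 and 7 of 20, 0.23) were not called either.

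**Figure D3:**
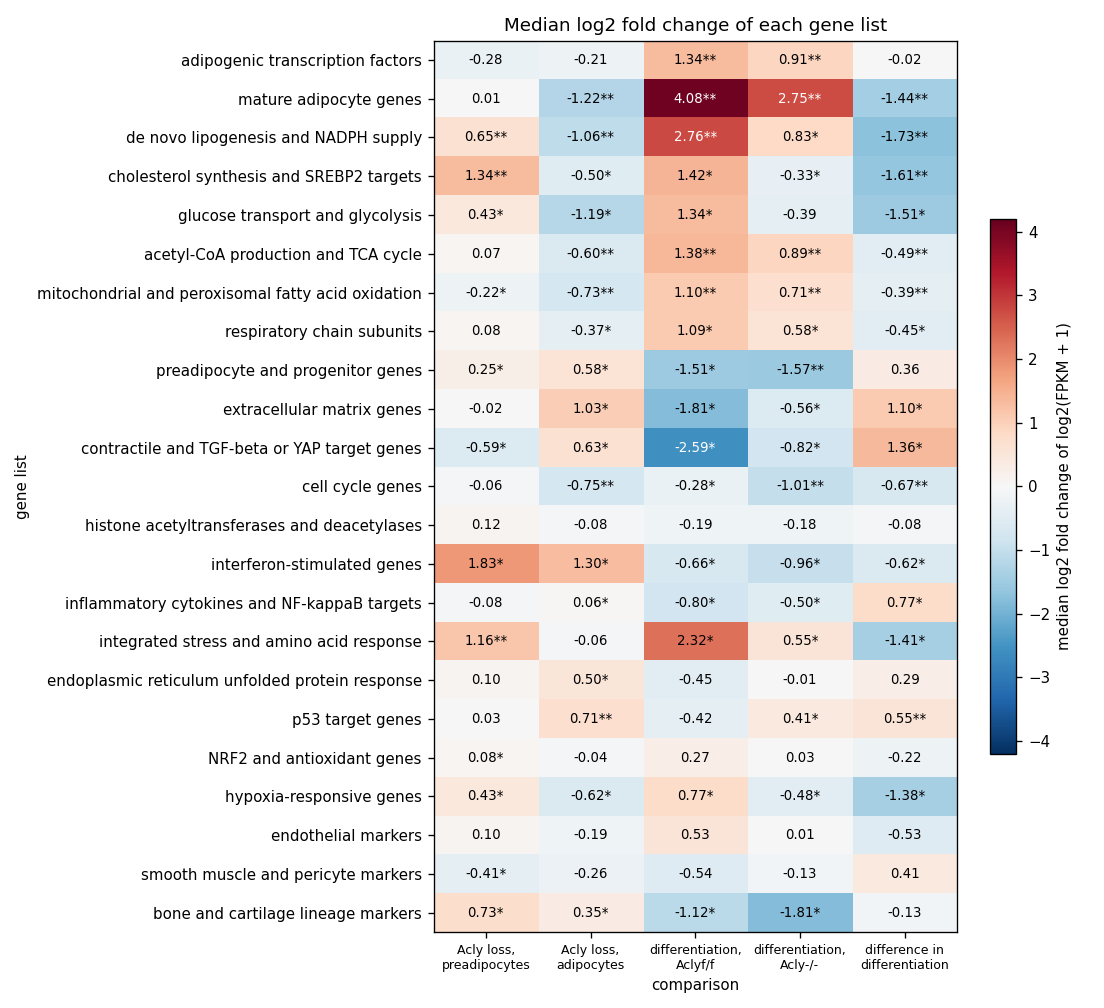
Median log2 fold change of log2(FPKM + 1) in each of 23 gene lists (vertical) for the 5 contrasts (horizontal), where the last column is the difference between both differentiation contrasts. One asterisk marks the 51 list tests called by camera with the preset correlation only, and a pair of asterisks the 27 that were also called with an estimated correlation.

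Of the 115 list tests, 78 were called with the preset correlation and 27 with an estimated one, all 27 being among the 78. Those 27 were lipogenesis, cholesterol synthesis and the integrated stress response for Acly loss in preadipocytes, and mature adipocyte, lipogenic, TCA, fatty acid oxidation, cell cycle and p53 genes for Acly loss in adipocytes. For differentiation they were transcription factors, mature adipocyte, TCA and fatty acid oxidation genes in both genotypes, lipogenic genes in Aclyf/f cells, and preadipocyte and cell cycle genes in Acly-/- cells. For the difference between contrasts they were mature adipocyte, lipogenic, cholesterol, TCA, fatty acid oxidation, cell cycle and p53 genes. Leaving out genes that share a locus ended the calls of cholesterol synthesis and SREBP2 targets in Acly-/- differentiation (0.0602), of hypoxia-responsive genes in Aclyf/f differentiation (0.0656), of bone and cartilage lineage markers in adipocytes and Aclyf/f differentiation (0.112 and 0.0945) and of NRF2 and antioxidant genes in preadipocytes (0.0871).

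Brown and beige adipocyte genes were mostly undetected, with 2 of 17 tested. These were Cox7a1, above, and the potassium channel gene Kcnk3, which was 3.9 ± 0.733 FPKM in Aclyf/f and 0.867 ± 0.102 FPKM in Acly-/- adipocytes (log2 fold change -1.38, adjusted p = 4.01e-07). In preadipocytes Cox7a1 was 1.02 ± 0.372 and 1.79 ± 0.488 FPKM (adjusted p = 0.0531), called with a pseudocount of 0.1 (0.0414), after quantile normalization (0.036) and without Aclyf/f preadipocyte library 1 (0.0291), Acly-/- preadipocyte library 2 (0.0274), Aclyf/f adipocyte library 3 (0.046) or Acly-/- adipocyte library 2 (0.0422).

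Markers of other cell types that were tested reached group means over 10 FPKM for Spp1, Cd68, Mcam and Runx2 among the genes named here. Of macrophage and leukocyte markers, 2 of 15 were tested, Cd68 and the endotoxin receptor gene Cd14, which was 3.63 ± 0.419, 3.32 ± 0.703, 1.36 ± 0.243 and 1.46 ± 0.313 FPKM in Aclyf/f and Acly-/- preadipocytes and Aclyf/f and Acly-/- adipocytes. In the same order Cd68 was 1.91 ± 0.466, 2.75 ± 0.718, 1.5 ± 0.344 and 32.6 ± 3.12 FPKM. Of 12 endothelial markers, 3 were tested, and the highest were Egfl7, at 3.6 to 5.74 FPKM in group means, and Sox18, at 0.01 to 2.48 FPKM. That list was not called in any contrast (adjusted p 0.584 to 0.995). Of 12 mesothelial and epithelial markers, 1 was tested, keratin Krt19, at 1.78 ± 0.28 FPKM in Aclyf/f and 5.13 ± 1.11 FPKM in Acly-/- preadipocytes and under 1 FPKM in adipocytes. Krt7 was at most 0.171 FPKM. Of 14 skeletal muscle markers, 2 were tested, Acta1 and Des, with group means of at most 3.86 and 1.46 FPKM. Of 10 smooth muscle and pericyte markers, 5 were tested. The adhesion molecule gene Mcam reached 19.4 ± 0.44 FPKM in Aclyf/f and 1.07 ± 0.0633 FPKM in Acly-/- adipocytes, and Myh11 6.96 ± 0.616 and 3.14 ± 0.355 FPKM. That list fell in 4 of 5 in Acly-/- preadipocytes (adjusted p = 0.0128, and 0.128 with an estimated correlation) and was not called in the other contrasts (0.0933 to 0.994). For the difference by genotype it had 3 positive and 2 negative members with a median of 0.41 but a mean of -0.19. Of 12 bone and cartilage lineage markers, 6 were tested. Osteopontin, Spp1, was 61.6 ± 6.89 and 183 ± 14.1 FPKM in Aclyf/f and Acly-/- preadipocytes and 3.22 ± 0.385 and 12.5 ± 2.89 FPKM in adipocytes, and Runx2 was 13.4 ± 0.401, 17.8 ± 0.907, 7.78 ± 0.802 and 14.1 ± 0.501 FPKM. Without Acly 5 of the 6 were higher and 1 lower in preadipocytes (adjusted p = 0.00498) and 3 of 6 higher in adipocytes (0.0352, and 0.0784 after quantile normalization), and 5 of 6 fell with differentiation in each genotype (0.0149 and 0.00645). None of these 4 calls held with an estimated correlation (0.0723 to 0.132), and the difference by genotype was not called (0.777).

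Short and non-polyadenylated RNAs were among the largest changes by size, and several depended on single libraries. Rpph1, the RNA of ribonuclease P, was 36.8 ± 50.4 and 2.26 ± 1.04 FPKM in Aclyf/f and Acly-/- preadipocytes and 5.17 ± 3.3 and 200 ± 149 FPKM in adipocytes, with 222, 336 and 40.6 FPKM in the 3 Acly-/- adipocyte libraries. Its log2 fold change was -2.54 in preadipocytes (SE 0.93, adjusted p = 0.0426), 4.77 in adipocytes (adjusted p = 0.000733) and 7.31 for the difference (adjusted p = 0.000506). The preadipocyte call ended without Aclyf/f preadipocyte library 3 (-1.34, adjusted p = 0.196) or 1 (0.0552), Acly-/- preadipocyte library 1, 2 or 3 (0.111, 0.0813 or 0.066) or Acly-/- adipocyte library 1 (0.0516). Rmrp, the RNA of a related ribonuclease, was 10.4 ± 4.03 and 99 ± 11.8 FPKM in Aclyf/f and Acly-/- adipocytes (adjusted p = 0.00363, and 0.00133 for the difference of 5.41). The spliceosomal RNA Rnu12 was listed at the floor of 0.01 FPKM in the other groups and at 10.8 ± 2.13 FPKM in Acly-/- adipocytes (adjusted p = 8.17e-11). Small nucleolar RNAs Snora81 and Snora74a were at the floor in Aclyf/f adipocytes and at 18.2 ± 9.81 and 12.8 ± 8.16 FPKM in Acly-/- adipocytes (adjusted p = 0.00256 and 0.00281). Snora23 was 8.97 ± 8.18 FPKM in Aclyf/f preadipocytes and at the floor in Acly-/- preadipocytes (adjusted p = 0.00296). Differences by genotype were 5.06 for Snora23 (0.000718), 4.12 for Snora81 (0.0223), 4.05 for the histone gene Hist1h4d (0.0179), 3.68 for Snora78 (0.0457), 3.60 for Snora74a (0.0214), -6.62 for Snora70 (0.00932) and -5.92 for Mir8112 (0.0275). Snora81 lost this call without Aclyf/f preadipocyte library 1 (0.0554) or 3 (0.0502) or Acly-/- adipocyte library 1 (0.0545), Snora74a without Acly-/- preadipocyte library 1 (0.0519) or Acly-/- adipocyte library 2 (0.0552), and Mir8112 without Acly-/- preadipocyte library 1 (0.0527) or 2 (0.0686) or Acly-/- adipocyte library 1 (0.0619). Snora78 lost it without Aclyf/f preadipocyte library 1 or 3, any Acly-/- preadipocyte or Aclyf/f adipocyte library, or Acly-/- adipocyte library 2 (0.0682 to 0.104).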

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

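The exchange of genotypes and the prediction for the scaling of interferon-stimulated genes were written before results were seen. Rescaling to the same FPKM sum and quantile normalization for lists were added afterwards. So were the tests of undifferentiated cells, adipocyte gene scaling, immune cells, gene length and carry-over. Results appear here because differentiation changed them differently in the 2 genotypes, by the difference between contrasts itself.

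Adipocyte genes gained less in Acly-/- cells, within 5908 genes whose change differed by genotype. If like day 0 Acly-/- preadipocytes, a share of undifferentiated cells would lower all induced genes to a similar fraction of the control level. Among 179 strongly induced genes, however, the quartiles of that fraction differed 3.72-fold, with G0s2 at 91.4% and Thrsp at 2.1%. Simulated replicate noise around a common fraction gave at most 1.11. Cells left undifferentiated after 4 days in the cocktail were not measured. Adipocytes were taken on day 4 only, so the timing of differentiation was not tested. The authors' scaling does not account for the lower adipocyte genes. For Acly loss in adipocytes, the mature adipocyte list kept a median of -1.20 or lower under 4 scalings. For the difference between contrasts its median was -1.44, and the rescalings shifted all genes tested by a median of 0.002 to 0.047. When genotypes were exchanged within stages, 1 of 100 arrangements drawn from 200, the real one, had as many calls. The exchange of all adipocyte genotypes alone was not among those drawn. The next highest, with all 3 adipocyte libraries and 1 preadipocyte library exchanged, reached 3396. Exchanged groups mostly mix libraries of both genotypes, which widens the spread within groups and lowers the count by itself. The exchange therefore cannot exclude chance division of the libraries as the source of the count. A smaller share of undifferentiated cells on top of gene-specific loss, and differences between the cell lines other than Acly, stay open.

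Interferon-stimulated genes were higher without Acly at both stages, with a difference between contrasts at an adjusted p of 0.00338, but with an estimated correlation the adjusted p was 0.0734 in preadipocytes, 0.16 in adipocytes and 0.553 for the difference. Immune cells in the cultures are argued against by the sum of 13 leukocyte markers other than Cd68 and Cd14, which was 0.731 FPKM in the higher Acly-/- group and 0.866 FPKM in Aclyf/f preadipocytes. The authors' scaling is argued against by a lowest median of 1.22 over both stages and 4 scalings, from the rescaling to the same FPKM sum. Whether Acly loss itself or another property of the Acly-/- line goes with these genes was not tested and stays open.

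Some short and non-polyadenylated RNAs, among them Rpph1, Rmrp and Rnu12, were higher in Acly-/- adipocytes. Snora70 lay at the floor of 0.01 FPKM in Acly-/- adipocytes and in Aclyf/f adipocyte library 1. Aclyf/f adipocyte libraries 2 and 3 had 30.3 and 27.2 FPKM. Gene length does not account for the rises, since 20 other short genes had a median log2 fold change of -0.003. For the histone part, carry-over of non-polyadenylated RNA in single libraries fits, since Aclyf/f preadipocyte library 3 had a median of 2.34 FPKM and Acly-/- adipocyte library 3 only 0.296 FPKM. For the other part it cannot be told, since 2 of 15 small RNAs, Rmrp and Rnu12, lay above the other 9 libraries in all 3 Acly-/- adipocyte libraries. A change in the cells was not tested apart from this and stays open.

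Other gene lists with a difference by genotype, at camera adjusted p, were mature adipocyte genes (8.55e-09), de novo lipogenesis and NADPH supply (2.88e-14), cholesterol synthesis (2.64e-16), glycolysis (3.42e-12), acetyl-CoA and TCA (9.43e-08), fatty acid oxidation (0.000371), respiratory chain (0.000725), extracellular matrix (1.33e-10), contractile genes (5.07e-07), cell cycle (1.26e-08), inflammatory genes (0.000902), integrated stress (3.48e-11), p53 targets (0.000392) and hypoxia (2.36e-07). With an estimated correlation 7 of these lost the call, glycolysis, respiratory chain, extracellular matrix, contractile genes, inflammatory genes, integrated stress and hypoxia.

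Differences by genotype on the log2 scale among the genes named were -3.08 for Acly, -3.64 for Acss2, -2.86 for Slc2a4, -3.16 for Mlxipl, -5.40 for Thrsp, -4.45 for Fasn, -4.43 for Trib3, -4.29 for Ndufa4l2, -4.27 for Cox7a1, -4.07 for Retn, -3.97 for Rbp4, -3.97 for Gpd1, -3.95 for Lrg1 and -2.75 for Lama4. Interferon-related genes had -1.36 for Mx1, -1.26 for Oas3, -1.16 for Zbp1, -1 for Cmpk2, -0.88 for Irf7 and -0.66 for Rsad2. Positive differences were 3.84 for Prl2c2, 3.39 for Cd68, 3.06 for Nov, 2.56 for Pamr1, 2.45 for Fbln7 and 0.90 for Tmem176b. Those of Nov, Pamr1 and Fbln7 mostly restate their preadipocyte changes of -2.73, -2.56 and -2.50. In Aclyf/f and Acly-/- adipocytes Nov was 0.524 and 0.926, Pamr1 0.01 and 0.01, and Fbln7 0.235 and 0.192 FPKM. Short RNAs and a histone gene had 7.31 for Rpph1, 5.41 for Rmrp, 5.06 for Snora23, 4.12 for Snora81, 4.05 for Hist1h4d, 3.68 for Snora78, 3.60 for Snora74a, 3.53 for Rnu12, -5.92 for Mir8112 and -6.62 for Snora70.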

How the results depend on the processing

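Settings chosen only after results were seen are named above. Among the settings tried, counts of called genes moved by over 1.5 times under 1 alone, a required absolute log2 fold change of at least 1, which left 602 genes for Acly loss in preadipocytes, 936 in adipocytes, 2766 and 1535 for differentiation in Aclyf/f and Acly-/- cells and 1459 for the difference between them. That setting is stricter by construction. With an estimated inter-gene correlation 27 of 78 list calls remained, and the cause was not tested. With fry the smooth muscle and pericyte markers took the opposite direction for the difference by genotype (adjusted p = 8.4e-05), and the cause was not tested. Leaving out 1 library at a time gave 4070 to 5111, 5675 to 6726, 8054 to 8708, 6567 to 7374 and 5310 to 5831 called genes in the order above, with 76 to 78 list calls and 0 changes of sign. Pseudocounts, filters, rescalings, quantile normalization and no variance trend kept every count within 1.5 times. Depth limits genes under 0.3 FPKM, which rest on few fragments.

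Replicates carry the same numbers in all groups. With a replicate block 4573, 6125, 8352, 6954 and 5516 genes and 77 lists were called. Residuals of the 18 pairs of libraries with the same number had a median correlation of -0.079 (range -0.41 to 0.15), those of 36 pairs with different numbers 0.026 (-0.17 to 0.42), and 0 of 12 libraries correlated best with their own number, so the numbers do not pair libraries in these data. Of 393 values for named genes, 388 kept their call under the block.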

Other observations

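Every gene and list in this paragraph and the next was chosen after results were seen. Lysosomal genes were higher in Acly-/- adipocytes, in 26 of 36 with 3 lower (median log2 fold change 0.47, camera adjusted p = 2.27e-08 over the 15 added tests, and 0.253 with an estimated correlation), and lower in Acly-/- preadipocytes, in 18 with 2 higher (median -0.25, 1.82e-05, and 0.306). Gpnmb, a membrane glycoprotein of lysosomes, was 164 ± 11 and 65.5 ± 3.99 FPKM (SD, n = 3) in Aclyf/f and Acly-/- preadipocytes and 12 ± 1.95 and 59.1 ± 7.28 FPKM in adipocytes. The cathepsin gene Ctsk was 19.5 ± 1.37 FPKM in Aclyf/f and 85.5 ± 4.84 FPKM in Acly-/- adipocytes, and the saposin precursor gene Psap 756 ± 32.4 and 1460 ± 14.7 FPKM. Cd68 is on this list too. Antigen presentation genes of MHC class I were higher in 13 of 13 in Acly-/- preadipocytes (median 1.10, 1.91e-08, and 0.306), but in adipocytes 3 were higher and 2 lower (median 0.03, 0.633), and the difference by genotype was negative in 10 and positive in 1 (0.000441, and 0.424). Among them was Tap1, the peptide transporter gene, at 31.7 ± 2.66 against 99.3 ± 20.9 FPKM in preadipocytes.

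Ribosomal protein genes were higher in Acly-/- adipocytes in 44 of 52 (median 0.48, 5.91e-11, and 0.371), the median being 0.24 under the scaling that gave the least. Ferritin heavy chain, Fth1, was 2710 ± 131 and 6130 ± 246 FPKM and the transferrin receptor gene Tfrc 10.3 ± 2.26 and 33 ± 3.49 FPKM in Aclyf/f and Acly-/- adipocytes. The linker histone gene Hist1h1c was higher without Acly at both stages, at 6.07 ± 1.03 and 28.8 ± 4.64 FPKM in preadipocytes and 18.3 ± 3.34 and 63.9 ± 8.17 FPKM in adipocytes. Carry-over of non-polyadenylated RNA, weighed above for the histone genes in single libraries, was not tested for this gene alone.

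The hypothesis about mature adipocyte genes was written before results were seen, and that about lipogenic genes after. For 13 induced lipogenic genes the median difference by genotype was -3.08, against -1.59 for random sets of equally induced genes, with a one-sided permutation p of 0.00072. That difference also holds their rise in Acly-/- preadipocytes (list median 0.65), and in adipocytes themselves the lipogenic list, at a median of -1.06, fell no more than mature adipocyte genes, at -1.22. Whether lipogenic genes depend more on Acly within adipocytes therefore stays open. Mature adipocyte genes outside the lipogenic list did not stand out, at -1.67 for 26 members against -1.60 for random sets of equally induced genes and a permutation p of 0.4. Members share regulators and are not independent, so these p-values hold for genes, not for cultures.

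Splits of libraries within each pair of groups were planned before results were seen. Of 10 ways to split the 6 libraries of a pair, 1, the real one, gave as many calls in each contrast, and the highest other count was 0 for Acly loss in preadipocytes, 1 for Acly loss in adipocytes, 0 for differentiation in Aclyf/f cells and 1 for differentiation in Acly-/- cells. With 10 splits no share under 0.05 can arise, so this test alone cannot tell.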
